A study of Mus musculus with 6 samples.

How the data were processed

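The arrays were custom Agilent protein binding microarrays, on which single-stranded probes are made double-stranded by primer extension and a tagged protein bound to a probe is read as fluorescence. Per the labels' protocols, the DNA-binding domains of GABPα, an ETS-family factor, and CREB1, a bZIP factor, were made with an N-terminal glutathione S-transferase (GST) tag by in vitro translation from 570 ng of plasmid in 250 µl at 37 °C for 2 h, and 230 µl of the reaction went onto each array. In the mixed reactions, 66 ng of a plasmid for CREB1 without GST was added to the 570 ng of GABPα plasmid, so that the tag read GABPα alone. The labels place 2 arrays in each of 3 groups, called here GABPα alone, GABPα with CREB1, and CREB1 alone. The labels do not say whether the 2 arrays of a group came from separate protein preparations, so the spread between arrays behind the p-values may be technical. The fits also share that spread across the sequences or substitutions tested together.

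Per the file headers, the deposited scanner files hold spot intensity in the Cy5 (red) channel on a linear scale, from Agilent Feature Extraction 12.0.1.1. The processed intensity had a fitted background surface subtracted and was detrended across the array by the scanner software, and a surrogate value stood where the subtracted intensity was not significant, per the file headers. The deposited value table holds intensity too: for each probe name, the median over its spots of the spot's median intensity minus the median of the local background. Recomputed so from the scanner files, all 6891 entries of each array were met within 0.01. That table is on a linear scale and is neither centred nor turned in direction. Its column medians were 325.25 and 338.5 for GABPα alone, 317.25 and 241.75 for GABPα with CREB1, and 16931.75 and 17398.0 for CREB1 alone.

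Each array held 179966 spots. Of these, 165480 carried 6889 custom sequences at 24 spots for most sequences, 7923 carried 3923 genomic sequences of the manufacturer's catalogue, and 6563 were controls, which were left out together with spots marked as outliers by the scanner software (2.26% to 4.55% per array). The genomic probes and negative controls lack the priming site of the custom probes. A sequence counted as above background where over 0.5 of its spots were well above background by the scanner software's test. That test was set at 13 standard deviations per the file headers, so a sequence called below background may still hold signal. Between 16.7% and 23.9% of sequences were above background on the 4 arrays with tagged GABPα, and 55.3% and 59.3% on the CREB1 arrays. The number of arrays limits the precision.

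The signal used here was log2 of the processed intensity minus each array's 75th percentile, averaged over the spots of a sequence. Because under 50 percent of sequences were above background on the GABPα arrays, the percentile was taken over spots of the 1143 sequences above background on all 6 arrays. This set was chosen after a first scaling over all spots had been seen to sit at the edge of the background, and the values with the percentile over all spots are given as an alternative. A substitution's effect was its log2 signal minus that of the unmutated site on the same array, so that scaling between arrays cancels. Sites were placed at the outer end, the middle or the inner end of the probe in both orientations, 6 placements in all, and effects were averaged over the 5 placements whose unmutated site was above background on every array. The outer forward placement was below background with GABPα alone and was left out of the average. That choice too was made after the values were seen, and the average over all 6 placements is an alternative, in which the gain at the 16-mer was 1.15 against 0.60. A substitution counted as above background by the mean share of such spots over the 5 placements, so single placements of it could lie at background. After the values were seen, doubles that were above background together with both their singles in each of the 5 placements were counted apart.

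Tests used limma 3.58.1 (lmFit and eBayes) in R 4.3.3 with Benjamini-Hochberg adjustment and a threshold of 0.05. The addition of CREB1 was tested on the 4 arrays with tagged GABPα over 10812 sequences. Effects of the 48 single substitutions and departures of the 1080 double substitutions from additivity on the log2 scale were tested in a fit of all 6 arrays with a mean per group, and the difference in a substitution's effect with and without CREB1 was tested on the 4 arrays. Lists of sequences, fixed before the data were examined by position in the site, were tested with camera (preset correlation) and fry, and after the values were seen also with camera and an estimated correlation. With 2 arrays against 2, an exact permutation test cannot give a p below 0.333, so none was run. Files were read and tabulated in R with the package data.table, version 1.17.8, and with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

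A sequence below background on every array of a group has only a bound there. Its difference from a brighter group is given as "at least N-fold": the bright group's mean log2 signal over its arrays against the dim group's mean of, per array, the higher of the lowest signal among sequences above background and the sequence's own signal. No fold is given where both groups lay below background. The bounds hold within the processed signal, and the deposited value table gave smaller differences for some sequences. Per the file headers, the first array of GABPα alone and the first with CREB1 shared a slide, and so did the second of each, so values within each slide are given as well. The CREB1 arrays were on other slides scanned on another day, so that CREB1 alone and scan day cannot be told apart. Signals of CREB1 alone were compared only with other probes on the CREB1 arrays, and those of substitutions with the unmutated site on the same array.

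The limma fits were tested on simulated values with known changes, drawn independently for each sequence or substitution with the arrays' own spread. The averaging of spots, the scaling, the surrogate values and the background floor were not simulated. The recovery and false calls therefore do not cover errors from those steps. Of 10812 sequences, 200 were changed by CREB1: at a log2 change of 0.5, 0 of 67 were recovered by limma, at 1.0 it was 43.3%, and at 2.0 it was 78.8%, with 5 false calls. Of 48 single substitutions, 24 were changed: all 8 at each size were recovered for GABPα alone, and 87.5% at 0.5 and 100% at 1.0 and 2.0 for the difference with CREB1. Of 1080 double substitutions, the 200 changed were recovered at every size, with 3 false calls for GABPα alone, 11 with CREB1 and 12 for CREB1 alone.

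The sequences named in the text follow a rule fixed before the data were examined. It takes the unmutated site; the 10 largest increases and decreases with CREB1 past the threshold whose arrays do not overlap; per group the 5 single substitutions with the largest and the 5 with the smallest loss; per group the 5 double substitutions with the largest positive and negative departure from additivity; the 5 single substitutions with the largest difference with CREB1 in each direction; and the highest and lowest member of each further family of sequences. After the values were seen, ranks of losses and departures were restricted to those measured above background. Differences with CREB1 were restricted to substitutions above background on both arrays of GABPα alone or of GABPα with CREB1. These differences were ranked by their fitted values, and not by bounds where GABPα alone lay below background. Sequences whose signal went to or from background with CREB1 were ranked apart by their bounds. Genomic sequences were not named. Other sequences named in the text were chosen after their values were seen: A1C, C2T, G8T, T9A and T9G, and the members of the shortened, shifted and trimmed series that mark a step. Some substitutions that the rule names in one group, such as G8C, C15A and A7C, were also given in another.

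Alternatives were background correction by normexp with an offset of 50, the median over spots, outlier spots kept, sequences below background left out, the replicate number as a block, each array left out in turn, an intensity trend in eBayes, each array's median, quantile or no scaling, the deposited value table, all 6 arrays in the fit, additivity on the linear scale, and doubles whose additive prediction was above background. Those added after the values were seen were the percentile over all spots, the separate placements and orientations, all 6 placements, custom sequences alone, a crossed pairing of the arrays, and the deposited value table without scaling or without dim sequences. The separate outer placement held the reverse orientation alone, since the outer forward placement was left out, while the middle and inner ones held both orientations. In the deposited value table, 387 sequences with a value at or below 0 were left out of fits on the log2 scale. Slide membership equals the replicate number in the GABPα groups, so the block serves for both there, and slide was also a random block in the fits of 6 arrays.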

Results

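The study measured how strongly the DNA-binding domains of mouse GABPα and CREB1 bound designed DNA, and whether CREB1 changes the binding of GABPα to a composite site. GABPα is an ETS-family transcription factor that recognises GGAA cores, and CREB1 is a bZIP factor that binds the cAMP response element (CRE), TGACGTCA. The composite site was the 16-mer ACCGGAAGTGACGTCA, whose positions are counted from 1 at its 5′ end. The ETS part is taken here as positions 1 to 8, position 9 is shared, and positions 10 to 16 complete the CRE. GST-tagged GABPα alone, GST-tagged GABPα made together with untagged CREB1, and GST-tagged CREB1 alone were compared on 2 arrays each. Only the tagged protein is seen, so the mixed reaction reports GABPα in the presence of CREB1. Each array carried the site with each of its 48 single and 1080 double substitutions in 6 placements, besides series in which the site was shifted, shortened or trimmed. The 2 arrays of a group correlated at r = 0.997 for GABPα alone, 0.997 for GABPα with CREB1 and 0.993 for CREB1 alone across the custom sequences, which are not independent replicates.

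The first comparison asked whether CREB1 changes the binding of GABPα to the intact composite site. GABPα gave a higher signal at the unmutated 16-mer in the presence of CREB1, by 0.60 on the log2 scale (SE 0.083), a 1.52-fold increase. The scaled log2 signal was -0.33 ± 0.01 (SD, n = 2) with GABPα alone and 0.28 ± 0.15 (SD, n = 2) with CREB1. The increase was 0.72 on the first slide and 0.49 on the second, and its adjusted p from limma was 3.46e-12. In the authors' deposited value table the background-subtracted intensity was 4533 and 8351 on the arrays with GABPα alone and 6696 and 8383 with CREB1. The direction of this value rests on the scaling between arrays: with the percentile taken over all spots it was -0.25 (adjusted p = 0.219), and with no scaling it was 0.39 (adjusted p = 0.564). In the authors' table it was 0.54 after scaling (adjusted p = 0.511), 0.27 without it (adjusted p = 0.632), and 0.54 with an adjusted p of 0.00757 where dim sequences were left out.

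The gain held across the places the site took on the probe. The 5 placements used in the average rose by 0.40 to 0.74, of which the middle forward placement passed over all sequences (0.74, adjusted p = 0.0492). At the outer forward placement, where the ETS part lies at the very end of the probe, GABPα alone was not well above background and its signal with CREB1 was at least 3.86-fold higher (adjusted p = 0.00417). When the 16-mer was shifted along the probe in steps of a single base, 22 of the 36 shifted sites were higher over all sequences and 36 of 36 when adjusted over the list alone. The increases ran from 0.52 to 1.44 in the forward and from 0.58 to 1.14 in the reverse orientation. The list as a whole did not pass with an estimated correlation (camera, adjusted p = 0.454), and its median of 0.79 fell to -0.06 with the percentile over all spots. In the planned tests it passed with the preset correlation (camera, adjusted p = 4.46e-28) and with fry (adjusted p = 0.0270). Among forward shifted sites, GABPα alone was lowest 1 base from the outer end (-1.27 ± 0.17, SD, n = 2). Among reverse ones it was highest there (0.99 ± 0.05, SD, n = 2) and lowest 19 bases from it (-1.28 ± 0.10, SD, n = 2).

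**Figure D1:**
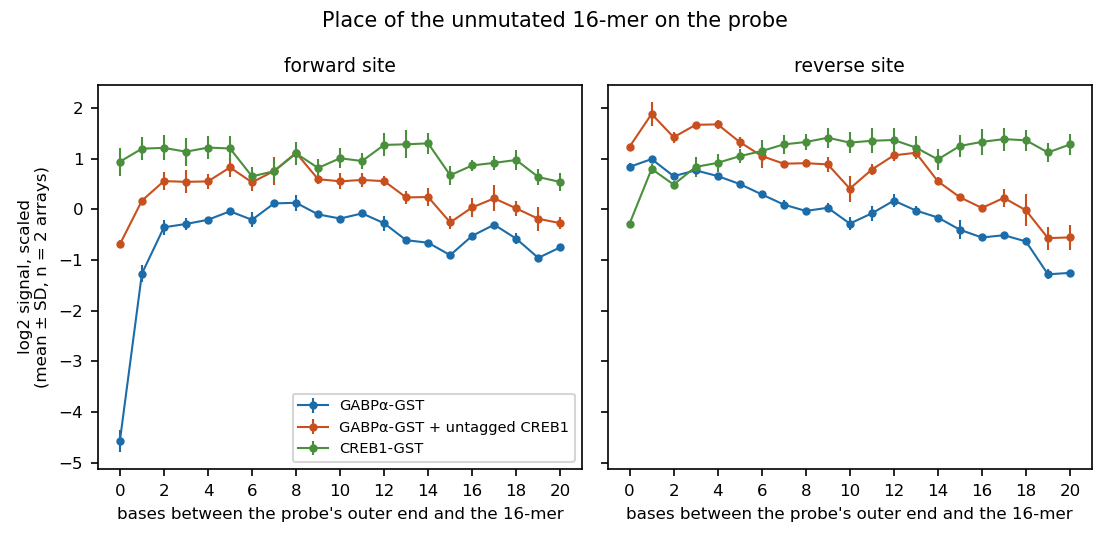
Scaled log2 signal (mean and SD of 2 arrays) against the number of bases between the outer end of the probe and the unmutated 16-mer, for forward and reverse sites. GABPα with CREB1 lies above GABPα alone at each offset under the scaling used here, and the forward site at offset 0 lies at -4.56 with GABPα alone and at -0.69 with CREB1.

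Across all sequences, 1115 of 10812 changed on the addition of CREB1, 728 higher and 387 lower (limma, adjusted p under 0.05). The number of lower calls varied widely between settings. Among custom sequences above background on all 4 arrays, 139 were higher and 337 lower. A further 372 were below background with GABPα alone and above it with CREB1, with a median of at least 2.14-fold. Of these, 322 carried a substitution at positions 1 to 8, as most custom sequences on the array do. Being below background with GABPα alone also selects such sites, so this share is not an enrichment. Only 2 custom sequences, A1G+A11C and T9C+A16C in the inner forward placement, went from above to below background, by at least 1.31-fold and 1.43-fold. The other calls were 197 custom sequences at or near background and 68 genomic sequences. In all 1047 called custom sequences the arrays of the groups did not overlap. Without selection 2 arrays against 2 do so by chance in 33.3% of cases. These sequences were called on the same arrays, so the lack of overlap adds no support. The largest measured increases were A1C+A16T (1.79 ± 0.079 SE, adjusted p = 0.00594), A1C+C15G (1.72) and A1C+C15A (1.68) in the middle forward placement, and A1G+G8A (1.67) in the middle reverse placement. The largest at-least increases were in forward probes with trimmed flanks, up to at least 5.79-fold, and in C2G+C15A (at least 4.86-fold) and A1T+C15A (at least 4.64-fold) in the middle forward placement. These bounds hold within the processed signal. In the authors' table after scaling the log2 increases were smaller than the bounds: 1.97 for the forward probe with 12 bases trimmed, 1.56 for C2G+C15A and 1.60 for A1T+C15A. The largest measured decreases lay in the outer reverse placement, with T9G+A11C at -1.11 (SE 0.079, adjusted p = 0.0140), T9G+C12A at -1.08, T9G+A16T at -1.07 and T9G+C12G at -1.01.

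The sites were then grouped by the place of their changes. Of the 144 sites with a single ETS substitution, 47 were higher and 0 lower over all sequences (53 and 2 when adjusted over the list alone), and 94 were below background in both groups. Of the 126 sites with a single substitution at positions 10 to 16, 20 were higher and 5 lower (32 and 14 over the list alone), with a median of 0.14. The median of the 118 of these above background in a group turned to -0.10 with no scaling. Of the 3024 sites with a substitution in each part, 455 were higher and 39 lower. Of the 1134 sites with both substitutions at positions 10 to 16, 242 were lower and 47 higher (489 and 68 over the list alone), with a median of -0.45 over the 975 that were above background in a group. Its median was negative under each scaling and on both slides, -0.34 and -0.51. Of the 810 sites with a change at position 9 and another, 51 were lower and 3 higher over all sequences, but 0 passed in limma when adjusted over the list alone. None of these 5 lists passed with an estimated correlation (camera, adjusted p = 0.824 for ETS singles and for doubles within positions 10 to 16, 0.580 for singles there, 0.975 for a change in each part and 0.824 for position 9). The number of calls depended on single arrays and on the processing. It was 0 in limma without the first array of GABPα alone (3571 at unadjusted p under 0.05) and 0 without the second (5818), 397 and 381 without the first and second arrays with CREB1, 443 with the replicate block, 595 after normexp, 401 with no scaling, and 0 in the authors' table (578 at unadjusted p under 0.05). With dim sequences left out of that table, 1010 of 2092 passed, 577 higher and 433 lower. Lower calls, 387 in the settings used, numbered 10 with the replicate block, which is also the shared slide, 2 after normexp, 15 with no scaling, 9 with the crossed pairing, and 3 and 5 without the first and second arrays with CREB1. Other settings raised them, to 4475 of 5411 calls with an intensity trend, 4055 of 5137 over custom sequences alone and 8790 of 9269 with the percentile over all spots. Quantile scaling gave 823 higher and 794 lower, leaving out dim sequences 732 and 779, and all 6 arrays in the fit 761 and 102. With the median over spots, outlier spots kept and each array's median, 245, 482 and 331 were lower.

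The next comparison asked which bases each protein needs. GABPα alone lost signal on every ETS substitution, while no loss at positions 10 to 16 passed the test. All 24 substitutions at positions 1 to 8 were lower, and 21 of them fell below background on both arrays, including all 12 in the GGAA core, where each loss was at least 3.51-fold in the processed signal. In the authors' table A7T, the mildest of these 12, kept 38.5% and 29.5% of the unmutated signal, a smaller loss than that bound. A1C fell below it on a single array. The mildest losses were G8A, at -0.70 ± 0.07 (SD, n = 2) or 1.63-fold, and A1G, at -0.996 ± 0.05 (SD, n = 2) or 1.99-fold. All 3 substitutions at the shared position 9 were lower, T9C by -1.58 ± 0.10 (SD, n = 2), or at least 2.37-fold since a placement of it lay at background, while T9A and T9G fell below background. Of the 21 substitutions at positions 10 to 16, 0 passed as lower and only G13T passed as higher (0.23 ± 0.04, SD, n = 2, adjusted p = 0.0289). The others there lay between -0.18 for G10C and 0.14 for C15A. Small effects are not excluded by this. G10C (-0.17 and -0.19) and T14C (-0.16 and -0.19) were lower on both arrays, and C15A was higher on both (0.13 and 0.15). The count of 28 came to 3 of 24 when sequences below background were left out, since most of the losses end at background.

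CREB1 alone showed the mirror pattern. All 21 substitutions at positions 10 to 16 and all 3 at position 9 were lower, and at positions 1 to 8 only 2 of 24 were, G8C (-0.51 ± 0.04, SD, n = 2) and G8T (-0.81 ± 0.04, SD, n = 2), at the base beside the CRE. The largest losses sat at the centre of the CRE: G13T at -3.46 ± 0.40 (SD, n = 2), C12A at -3.33 ± 0.44 (SD, n = 2), A11C at -2.75 ± 0.37, G13C at -2.65 ± 0.37 and C12G at -2.57 ± 0.26 (SD, n = 2 each). All but C12G had placements at background, and counted at the lowest signal above background there the losses were at least 10.7-fold, 9.94-fold, 6.29-fold and 6.09-fold. Averaged over the 3 substitutions at a position, the loss was -1.62 at position 9 and ran from -1.31 at position 10 through -2.07, -2.49 and -2.61 at positions 11 to 13 to -1.44 at position 14, and then to -0.61 and -0.68 at positions 15 and 16. C15A was the mildest at -0.34 ± 0.03 (SD, n = 2). ETS substitutions such as A6T (0.06), C3G (0.04) and A6C (0.04) left values that did not pass the test. On the CREB1 arrays 23.9% and 25.0% of the spots of the unmutated site were saturated in the middle reverse placement and 4.44% and 25.5% in the inner reverse placement, which compresses the losses measured there.

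With CREB1 present, GABPα depended on both parts of the site. Of the 21 substitutions at positions 10 to 16, 20 lowered its signal, with C15A as the exception (0.07, adjusted p = 0.493), and all 24 at positions 1 to 8 and all 3 at position 9 did so too. The CRE losses were moderate, up to G10C at -1.15 ± 0.03 (SD, n = 2) and A11C at -1.12 ± 0.04 (SD, n = 2), a 2.22-fold and a 2.17-fold loss. Of the ETS substitutions, 9 stayed above background, against 2 with GABPα alone. Among them C2A was lower by 2.66-fold (-1.41 ± 0.14, SD, n = 2), C3A by 2.66-fold (-1.41 ± 0.12, SD, n = 2), C2G by 2.30-fold (-1.20 ± 0.11, SD, n = 2) and G8C by -2.15 ± 0.20 (SD, n = 2), or at least 4.32-fold with placements at background. Leaving out dim sequences left 30 of 31.

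**Figure D2:**
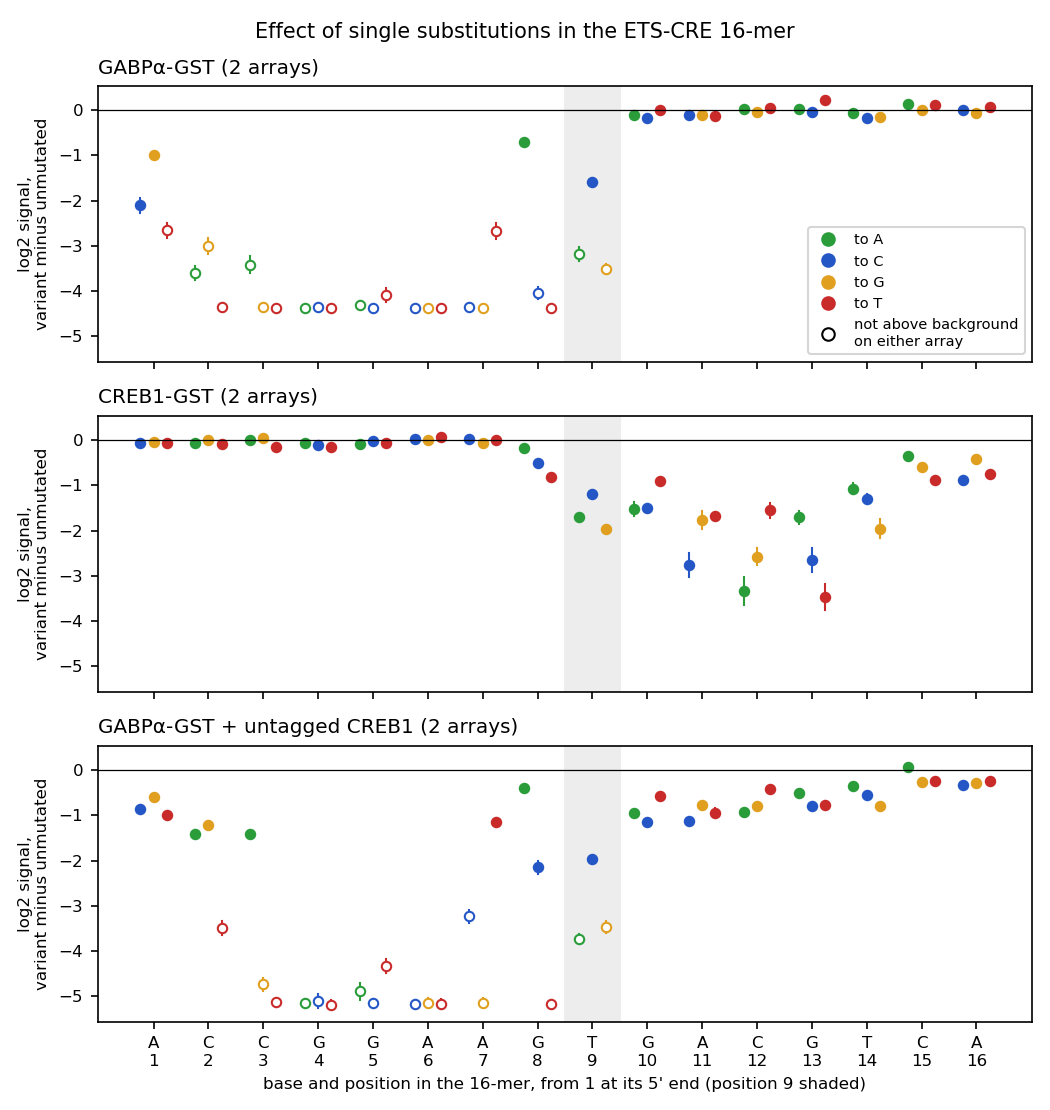
Log2 signal of each single substitution minus that of the unmutated 16-mer by position, for GABPα alone (top), CREB1 alone (middle) and GABPα with CREB1 (bottom). Points are means of 2 arrays, lines join the arrays, colours give the new base and open points were not above background on either array. GABPα alone stays between -0.18 and 0.23 at positions 10 to 16, where CREB1 alone falls to -3.46 and GABPα with CREB1 to -1.15.

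The test of the difference itself, each substitution's effect with CREB1 minus its effect with GABPα alone, passed for 45 of 48. In the CRE, 20 of 21 substitutions had a lower effect with CREB1, all of them above background on all 4 arrays. The largest were A11C (-1.02, SE 0.048, adjusted p = 0.00100), G13T (-0.995, SE 0.081), G10C (-0.97, SE 0.046), C12A (-0.97, SE 0.043) and G10A (-0.84, SE 0.050), and each was negative on both slides. In the ETS part, all 9 substitutions above background on both arrays of a group lost less with CREB1. Against the bounds of the loss with GABPα alone the differences were at least 0.15 to 0.76. Only 2 of the 9, A1G (0.41) and G8A (0.31), were above background on both arrays of GABPα alone. The others entered the set through their signal with CREB1, so a smaller loss was largely built in for them. The largest fitted values were C2A (2.19, SE 0.14, adjusted p = 0.00137), C3A (2.01, SE 0.16), G8C (1.90, SE 0.15), C2G (1.80, SE 0.155) and A1T (1.67, SE 0.14). These 5 were below background with GABPα alone, so the fitted differences lean on surrogate values. Against the bounds of the loss with GABPα alone, the difference was at least 0.64 for C2A, 0.53 for C3A, 0.15 for G8C, 0.73 for C2G and 0.76 for A1T. It was at least 0.70 for A1C and 0.66 for A7T. By these bounds A1T comes first and G8C last of the 9, so the order of the fitted values is not established. The 12 ETS substitutions with a lower fitted effect were all below background with and without CREB1 and have no measured difference, and the same holds for C2T and A7C, whose fitted effect was higher. At position 9, T9C had a lower effect with CREB1 (-0.40, SE 0.069, adjusted p = 0.00768), a value that leans on placements at background in both groups. In the authors' deposited values, 17 of 46 differences passed, 0 of them higher in limma (30 of 46 in either direction at unadjusted p under 0.05), and with dim sequences left out 28 of 31 did, 7 higher and 21 lower. In that table C2A kept 25.0% and 16.1% of the unmutated signal with GABPα alone and 43.6% and 45.6% with CREB1, and G13T gave 119% and 110% against 59.1% and 66.8%.

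Among variants changed in the CRE alone, the effect of CREB1 on GABPα followed how well CREB1 itself bound the variant. Across the 210 variants changed at positions 10 to 16 alone, the log2 change of GABPα on adding CREB1 correlated with the CREB1 signal at r = 0.924 (Spearman rho = 0.844), and at r = 0.909 and 0.921 within the slides. Over all 287 variants above background on the 4 arrays with tagged GABPα it was r = 0.845 (rho = 0.870), and over all 1129 variants, most of them below background with tagged GABPα, r = 0.354 (rho = 0.424). These are correlations across sequences, which are not independent replicates, and no array lies on both axes. The variants changed at positions 10 to 16 alone whose CREB1 signal was over 4-fold below that of the unmutated site had a median change of -0.49, that is, a lower scaled GABPα signal with CREB1 than without. The level that counts as no change rests on the scaling, and a difference in brightness between whole arrays is not excluded.

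**Figure D3:**
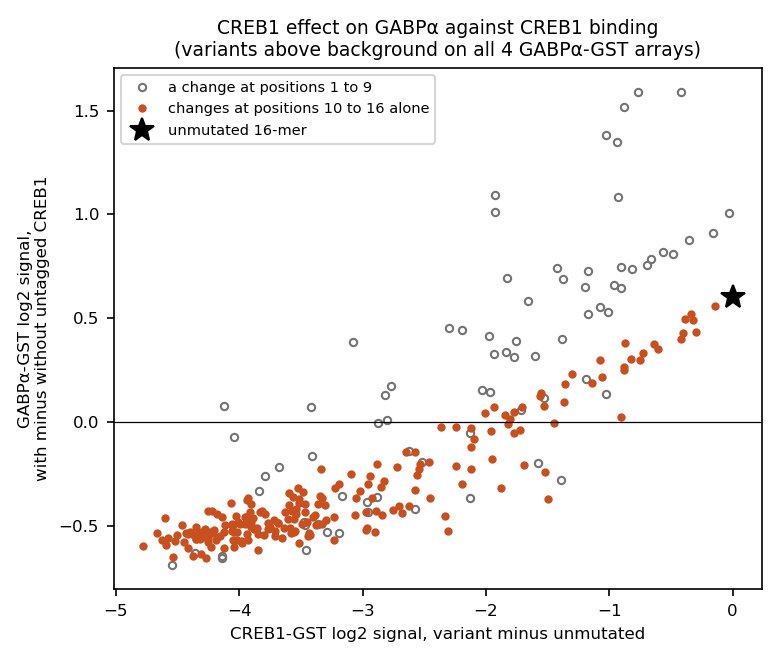
Change in GABPα log2 signal on adding CREB1 (means of 2 arrays per group) against the CREB1 log2 signal of the same variant relative to the unmutated 16-mer, for the 287 variants above background on all 4 arrays with tagged GABPα. The 210 variants changed at positions 10 to 16 alone (filled) rise along a curve with r = 0.924, from a median of -0.49 for those over 4-fold below the unmutated site on the CREB1 arrays to the unmutated site (star) at 0.60.

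Double substitutions tested whether effects of single bases add on the log2 scale. For GABPα alone, 404 of 1080 doubles departed from additivity, 357 positive and 47 negative, and most of the positive ones lay where a double cannot fall below the background already reached by a single. Among the 252 doubles above background together with both their singles, 7 were positive and 9 negative. The largest negative departures joined G8A to a change at position 10 or 11: G8A+G10C at -1.03 ± 0.18 (SD, n = 2, adjusted p = 2.01e-06), G8A+A11T at -0.86 ± 0.08 (SD, n = 2) and G8A+G10T at -0.80 ± 0.26 (SD, n = 2). The largest positive ones were T9C+G13T at 0.35 ± 0.05 and A1G+G13T at 0.31 ± 0.01 (SD, n = 2 each). Each of these 5 had a placement at background in the double or in G8A, A1G or T9C, so the departures are not exact. Among the 189 doubles above background with their singles in all 5 placements, all within positions 10 to 16, 1 passed. Within positions 10 to 16, 188 of 189 doubles did not pass for GABPα alone. Of the 21 singles there 20 did not pass either, so there was little to add and additivity was hardly tested. With dim sequences left out, 15 of 252 passed, and 17 of 257 where the additive prediction lay above background. With the authors' values 181 of 862 did.

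CREB1 alone departed from additivity on the log2 scale at 405 of 1080 doubles, 118 positive and 287 negative. The direction depends on the scale and on the placements used. On the linear scale 325 were positive and 14 negative, with the sign turned in 198 of the 405. In the outer reverse placement alone 227 were positive and 123 negative. There no spot of the unmutated site was saturated, but its signal was also the lowest. The forward middle and forward inner placements held no saturated spot of it either, so saturation alone does not set the outer reverse one apart. On the log2 scale, substitutions in both arms of the CRE lost more than the sum of their effects: with a change in TGAC (positions 9 to 12) and another in GTCA (positions 13 to 16), 73 of the 78 measured doubles were negative and 4 positive, with a median of -0.95. Saturated spots of the unmutated site in the middle and inner reverse placements lower its value, which pushes departures negative. How much of the median this makes up was not tested. Examples are T9A+A16T at -1.45 ± 0.18 (SD, n = 2, adjusted p = 1.64e-06) and G10A+A16T at -1.42 ± 0.00 (SD, n = 2), both with some placements at background. Where the double and its singles were above background in all 5 placements, 17 of 19 were negative and 2 positive, with a median of -0.87. Changes of adjacent bases went the other way, with 54 of 125 measured doubles positive and 3 negative. Of the 93 above background in all 5 placements, 27 were positive and 1 negative. T9A+G10C was the largest, at 1.82 ± 0.13 (SD, n = 2, adjusted p = 8.54e-07): the double changed by -1.38, less than T9A on its own (-1.71). A11C+C12G followed at 1.62 ± 0.03 and G10A+A11C at 1.57 ± 0.16 (SD, n = 2 each), with some placements at background. The middle placement alone gave 249 departures, and the authors' values 235 of 862.

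GABPα with CREB1 departed from additivity at 854 of 1080 doubles, 598 positive and 256 negative. Within positions 10 to 16, 93 of 189 doubles were positive and 10 negative, and 90 and 10 of the 185 above background in all 5 placements, so that on the log2 scale a second CRE change often added less than its single effect. G10A+A11C departed by 0.93 ± 0.05, G10A+G13T by 0.85 ± 0.14 and A11C+C12A by 0.85 ± 0.04 (SD, n = 2 each). With a change in each part, 63 of the 134 measured doubles were negative and 0 positive in limma, but only 5 of the 73 above background in all 5 placements were negative. The largest, C3A+G10T, A1T+A11T and A1T+C12A, had placements at background and have no exact departure. The positive majority shrank or turned in some other settings. Leaving out dim sequences gave 106 positive and 92 negative of 356, restricting to predictions above background 104 and 160 of 424, and the authors' values 176 and 268 of 862. With dim sequences left out, the authors' values gave 137 positive and 39 negative of 356. On the linear scale the majority grew, to 994 and 27, with the sign turned in 241 of the 854.

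Sites were next shortened from their outer end to see where each protein lost its signal. The outer flank then stood in place of the removed bases, so the steps hold for this flank. In the forward orientation the ETS end was removed first. With 1 base removed GABPα alone kept -0.14 ± 0.09, the flank then restoring the 16-mer, and with 2 removed it was below background. With CREB1 the site lacking 2 bases still gave -1.25 ± 0.03, at least 2.61-fold higher (adjusted p = 0.00363), and from 3 removed onward it was below background as well. CREB1 alone kept its signal until 8 bases were removed (1.02 ± 0.30), fell to -0.55 ± 0.27 at 9 and was below background from 12 (SD, n = 2 throughout). In the reverse orientation the CRE end was removed first. The signal of CREB1 alone went from 0.61 ± 0.20 with 3 bases removed to -1.91 ± 0.28 with 4 (SD, n = 2). At the same step GABPα with CREB1 went from 0.37 ± 0.17 to -0.24 ± 0.09 (SD, n = 2), below GABPα alone at 0.35 ± 0.02 (SD, n = 2), a change with CREB1 of -0.60 (adjusted p = 0.0353). With 5 and 7 bases removed that change was -0.46 (adjusted p = 0.0437) and -0.59 (adjusted p = 0.0235), and with 6 and 8 it was -0.70 (adjusted p = 0.0604) and -0.58 (adjusted p = 0.0830). GABPα alone held 0.43 ± 0.05 with 8 bases removed and was below background with 9 (SD, n = 2). The change with CREB1 at 4 removed bases was -0.52 and -0.68 within the slides and stayed negative under each scaling, while the increase of 0.29 at 3 removed bases did not pass (adjusted p = 0.120).

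**Figure D4:**
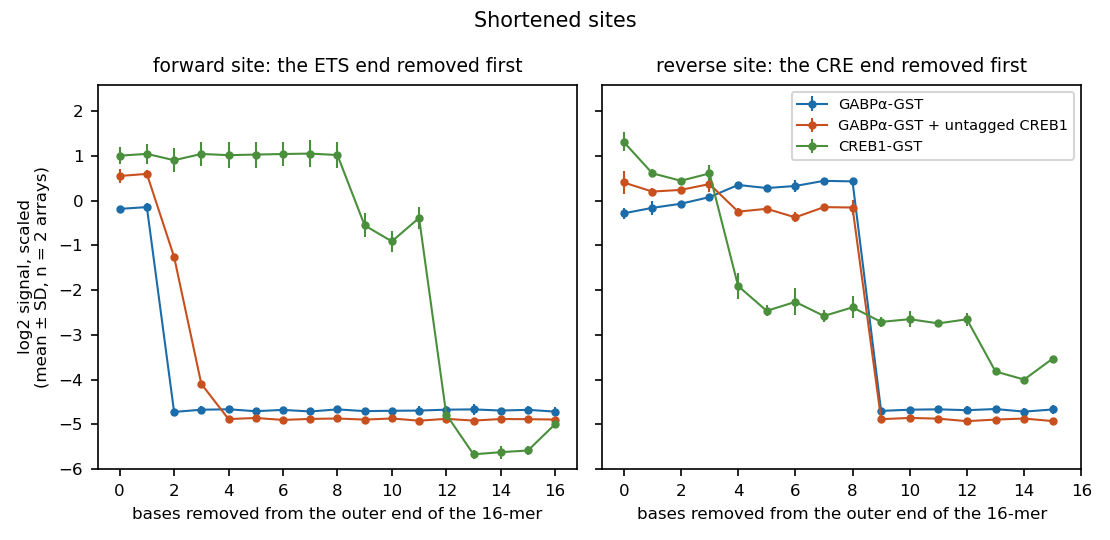
Scaled log2 signal (mean and SD of 2 arrays) against the number of bases removed from the outer end of the 16-mer, forward sites (left, ETS end first) and reverse sites (right, CRE end first). With 4 bases removed in the reverse orientation CREB1 alone drops to -1.91 and GABPα with CREB1 to -0.24, under GABPα alone at 0.35; values near -4.7 to -4.9 for GABPα are below background.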

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

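All tests of explanations in this part were chosen after the results they bear on had been seen. The effect of 10 single substitutions on GABPα differed with and without CREB1 by the test of the difference itself. The differences on the log2 scale were -1.02 for A11C, -0.995 for G13T, -0.97 for G10C, -0.97 for C12A and -0.84 for G10A in the CRE. In the ETS part the fitted values were 2.19 for C2A, 2.01 for C3A, 1.90 for G8C, 1.80 for C2G and 1.67 for A1T. These ETS substitutions were below background with GABPα alone. Against the bounds of that loss their differences were at least 0.64, 0.53, 0.15, 0.73 and 0.76, in the same order.

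In the CRE, substitutions with little effect on GABPα alone lowered its signal where CREB1 was present. A background floor is argued against, since 20 of the 21 substitutions were above background on all 4 arrays and kept a lower effect. A read-out of untagged CREB1 by the label is argued against as well: 5 of 5 sites with an intact CRE and no ETS core, bright on the CREB1 arrays, were below background with GABPα and CREB1 together. Dependence on CREB1 occupancy of the CRE had the values it needs, with r = 0.924 between the gain and the CREB1 signal across 210 variants. The hypothesis that CREB1 bound to the CRE may help GABPα onto the neighbouring ETS part was found and tested on the same data, and the amounts of protein on the arrays were not measured.

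In the ETS part, substitutions lost less GABPα signal with CREB1, while those at the core appeared to lose more. The latter is a matter of the floor: 9 of 9 substitutions at positions 4 to 6 were below background on all 4 arrays. A limit of the scanner's range with CREB1 is argued against, since 51 custom sequences were brighter on both of those arrays than the unmutated site in the middle forward placement. A limit on occupancy of the intact site within a placement cannot be judged from this. The unmutated site itself stood at 0.55 in that placement and at 1.24 in the outer reverse placement with CREB1. The surrogate values that replace signals below background could enlarge the smaller losses, and in the authors' table, which holds none, 7 of 9 substitutions kept a smaller loss on both slides. The 2 exceptions, each on the first slide only, were A1G (67.4% alone and 66.7% with CREB1) and G8A (78.1% and 75.1%), the only ones of the 9 above background on both arrays of GABPα alone. All 7 that fell below it on an array kept the smaller loss. This leaves the size of the ETS differences open, and whether CREB1 offsets a weak ETS part remains a hypothesis.

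Among the 3923 genomic sequences, whose CREB1 signal no comparison above uses, 17 were above background on both CREB1 arrays. None of the 67 genomic sequences with TGACG or its complement was among them, and these probes lack the priming site.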

How the results depend on the processing

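Of 197 results under alternative settings, 35 changed the sign or the side of the threshold at the 16-mer, or a count by more than 1.5 times; a count can hold while its direction turns. By that measure the 26 single substitutions of CREB1 alone held in 21 of 21, GABPα alone in 19 of 21, GABPα with CREB1 in 19 of 21, the differences with CREB1 in 18 of 20, the gain at the 16-mer in 21 of 25, the doubles in 18, 20 and 19 of 23 for GABPα alone, CREB1 alone and both, and the number of sequences changed by CREB1 in only 7 of 20. The gain at the 16-mer of 0.60 was 0.54 in the authors' table (adjusted p = 0.511), 0.39 with no scaling (0.564), 0.27 in the authors' table without scaling (0.632), -0.25 with the percentile over all spots (0.219) and 1.15 over all 6 placements (1.09e-52), over a range of adjusted p from 1.09e-52 to 0.632. Scaling alone separates 0.60 from 0.39 and -0.25; what costs the call in the authors' table was not tested, and leaving out its dim sequences gave 0.00757. The median change over all sequences was -0.18 in the scaling used, -0.39 with no scaling and -1.04 with the percentile over all spots, which stood at the edge of the background. The count of 1115 became 595 with normexp, 443 with the replicate block, 5411 with an intensity trend, 0 in the authors' table with and without scaling (limma, 578 and 1586 at unadjusted p under 0.05, and 1010 of 2092 with scaling and without dim sequences, 577 higher and 433 lower), 401 with no scaling, 468 with the crossed pairing, 9269 with the percentile over all spots and 5137 over custom sequences; the cause was not tested. Lower calls, 387 in the settings used, numbered 2, 10, 15 and 9 with normexp, the replicate block, no scaling and the crossed pairing, and 4475 with the trend. Quantile scaling gave 1617, 823 higher and 794 lower, leaving out dim sequences 732 higher and 779 lower, and all 6 arrays in the fit 761 and 102. Leaving out dim sequences, which tests fewer, gave 3 of 24 single substitutions for GABPα alone and 30 of 31 with CREB1 (3 and 30 in the authors' table as well), and 15 of 252 and 198 of 356 doubles. With the authors' values, 17 differences with CREB1 passed (28 without dim sequences), and 181, 235 and 444 doubles for GABPα alone, CREB1 alone and both (4, 170 and 176 without dim sequences, the last with 137 positive and 39 negative); the cause was not tested. Doubles came to 614 for GABPα alone on the linear scale, 17 and 264 for GABPα alone and with CREB1 where predictions lay above background, and 249 for CREB1 alone in the middle placement. Directions turned within counts that held: 325 positive and 14 negative for CREB1 alone on the linear scale (198 signs changed), 227 and 123 in the outer placement (136), and for both proteins 994 and 27 on the linear scale (241), 370 and 252 with normexp (159), 620 and 194 in the outer placement (94) and 665 and 224 in the inner (80). Other counts of doubles that held had at most 51 signs changed. The outer placement in these settings is the outer reverse one alone, so placement and orientation cannot be told apart there. The differences with CREB1 in it were 5 higher and 34 lower (5 signs changed), against 11 higher in the settings used. Leaving out each array in turn gave 0 to 397 changed sequences (0 without either array of GABPα alone, 397 and 381 without the first and second arrays with CREB1), 0.50 to 0.71 at the 16-mer, 27 to 33, 25 to 26 and 44 to 47 single substitutions for GABPα alone, CREB1 alone and both, 41 to 42 differences, and 332 to 416, 292 to 404 and 749 to 862 doubles. Where an arm kept a single array, it was assumed to vary like the others. Deviations of same-numbered GABPα arrays from their group means correlated at -0.24, although the numbers are slides, so a crossed pairing was added: it called 468 sequences against 443 for the replicate block, and 46 against 40 differences. The other counts with the replicate block stayed within 1.5 times. Centring on background sequences was not run, since the array holds 7 of the 20 required. The settings added after the data were seen are named with the processing.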

Other observations

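The test of less GABPα protein and the scaling test in this part were chosen after the values were seen. The arrays also carried 4 sites of 15 bases in which the 8-base CRE is cut to a 7-base element. The signal of GABPα alone ran from -0.06 ± 0.08 for TGACTCACTTCCGGT to 0.12 ± 0.02 (SD, n = 2) for TGAGTCACTTCCGGT. At the 16-mer in the middle placements, behind the same outer flank, it was -0.18 forward and -0.28 reverse. CREB1 alone ranged from -1.15 ± 0.14 for TGACTCACTTCCGGT to -2.86 ± 0.49 (SD, n = 2) for ACCGGAAGTGAGTCA. With CREB1 alone the unmutated 16-mer behind the same outer flank gave 1.01 forward and 1.32 reverse, and -0.28 in the outer reverse placement, where it was lowest. With CREB1, GABPα was lower at ACCGGAAGTGACTCA (-0.41, adjusted p = 0.0468), and the other 3 sites had values of -0.19 to -0.31 that did not pass over all sequences, while 3 of 4 passed when adjusted over the list alone. Their median of -0.26 was negative under each scaling, and the list did not pass with an estimated correlation (camera, adjusted p = 0.824). In the planned tests it passed with fry (adjusted p = 0.0270) and not with the preset correlation (camera, adjusted p = 0.136).

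Trimming the flanks outside the 16-mer left the gain with CREB1 in place. Of 40 trimmed probes 16 were higher over all sequences and 38 when adjusted over the list alone, with a median of 0.74 that was -0.11 with the percentile over all spots, and the list did not pass with an estimated correlation (camera, adjusted p = 0.454). In the planned tests it passed with the preset correlation (camera, adjusted p = 7.40e-28) and with fry (adjusted p = 0.0270). In the forward orientation GABPα alone was not well above background with 10 to 14 bases trimmed, where the ETS part lies at the end of the probe, and with CREB1 the probe with 12 trimmed gave -0.10 ± 0.09 (SD, n = 2), at least 5.79-fold higher (adjusted p = 0.0257). In the authors' table after scaling the increase of that probe was smaller, 1.97 on the log2 scale. In the reverse orientation, with the CRE at the end, 13 trimmed bases gave the highest signal of the series, 1.47 ± 0.02 for GABPα alone and 2.14 ± 0.07 with CREB1 (SD, n = 2 each). In 4 probes with a dinucleotide repeat in place of the site, GABPα was below background with and without CREB1, and CREB1 alone ranged from -3.70 ± 0.56 for CT, above background on a single array, to -2.23 ± 0.40 for CG (SD, n = 2).

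Of the 1134 sites with 2 changes at positions 10 to 16, 242 had less GABPα signal with CREB1 than without and 47 had more, and the list did not pass with an estimated correlation (camera, adjusted p = 0.824). In the planned tests it passed with the preset correlation (camera, adjusted p = 0.000429) and with fry (adjusted p = 0.0270). With the replicate block, which is also the slide, lower calls over all sequences numbered 10 against 387. Scaling between arrays is argued against as the whole account of their negative median, because the unscaled within-slide medians in the authors' table were both negative, the higher of them -0.33. A difference in brightness between whole arrays is not excluded, since unscaled values keep it. Less GABPα protein made beside CREB1 in the shared reaction could lower all sites alike: the 170 variants with a CREB1 signal over 4-fold below the unmutated site had a median change of -0.49 with an SD of 0.13. Their unscaled medians on the slides in the authors' table, -0.43 and -0.96, were unequal, and no array measured the amount of protein, so this explanation and an effect of CREB1 at damaged sites cannot be told apart.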
